A study of Mus musculus with 24 samples.

How the data were processed

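Chromatin from forelimb and hindlimb buds of C57BL/6J mouse embryos was crosslinked with formaldehyde and immunoprecipitated for 2 modifications of histone H3 lysine 27. Acetylation (H3K27ac) is found at active promoters and enhancers, and trimethylation (H3K27me3) is laid down by Polycomb repressive complexes. The series lists 24 samples, of which 10 had peak lists used here: 2 H3K27ac and 2 H3K27me3 libraries per limb at embryonic day 10.5 (E10.5), and 1 H3K27ac library per limb at E11.5. The 10 input and 4 mRNA samples were not analysed here. Samples were grouped by limb, stage and mark as their labels give them. Per the labels, the H3K27ac and H3K27me3 libraries differed in run type (paired-end against single-end), and the H3K27ac antibody lot differed between E10.5 and E11.5. Mark and run type, and stage and lot, therefore cannot be told apart. The protocol text of the E11.5 samples names day 10.5, while their titles and stage labels give 11.5, and the titles were followed. The labels do not say whether replicates came from separate litters, so spread and p-values cover these libraries and may be technical.

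Per the submitters' processing notes, reads were aligned to the mouse genome build mm9 with Bowtie 0.12.3 and peaks were called with MACS 1.37. Per the file headers, the E10.5 lists hold MACS peaks at a p-value threshold of 1e-05. There is 1 list per library, so replicates were not pooled. Each E10.5 peak carries a score from the authors' caller, deposited with the list, that equals -10 times the base-10 logarithm of the peak's p-value. The lowest score was 50 in each of the 8 lists to the nearest whole number, which is the value of that threshold. Scores were used only to rank and filter peaks within a list. The 2 E11.5 lists carry no header and no score, and their threshold is not given in the sources used here. Neighbouring peaks of the E11.5 lists are at least 1001 bp apart, against 1 or 2 bp in the E10.5 lists, so peaks lying closer than that appear to have been joined at E11.5. Peak numbers, widths and covered bases are for this reason not comparable between the stages. Which input served as the background of each list is not given in the sources used here. Sequencing depth is not in peak lists and is unknown, so a longer list can reflect deeper sequencing or stronger enrichment, and absence of a peak means only that no interval passed the authors' threshold.

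Peaks of the 4 E10.5 libraries of a mark were merged into a union at gap 0, and a region counted as detected in a library when at least 1 bp of it was covered. Limb-only regions were those detected in both libraries of 1 limb and in neither of the other. Their number was compared with the same count for the other ways of splitting 4 libraries into pairs. There are 3 such splits, so no exact p below 0.333 can be had, and words for change are not used of single regions. Similarity was the base-pair Jaccard index. Overlap of the marks was counted over regions detected in both replicates of a limb and compared with 1000 circular shifts of the H3K27ac regions within each chromosome, with a two-sided permutation p. E11.5 status of limb-only regions, and H3K27me3 within 10 kb of them, were tested with Fisher's exact test, two-sided. Regions are the units of these tests, neighbouring regions are not independent, and the p-values describe these lists. Covered bases were also summed in 20 kb bins. A bin was called where both libraries of 1 limb covered at least 4 kb more than both of the other. This rule was chosen after the lists had been seen.

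No mm9 gene models were used here. Genes are therefore given only as 18 windows around loci of limb development and controls, placed from general knowledge of mm9 before the data were examined. A table of the GRCm38.p6 assembly served to check them. All 18 lay on the table's chromosome, and the windows of all 7 chromosomes followed the table's order, which does not check their bounds. The window of Tbx5 begins inside the marked interval there, so its covered bases are an undercount. Gene sets, promoter states and markers of other cell types were planned for mm9 gene models only and were not run, and exon or intron positions are not given. Named regions were fixed by rule before the data were examined. They are, per mark, the 10 forelimb-only and 10 hindlimb-only regions with the best mean within-list score rank, the 10 longest H3K27me3 regions of all 4 libraries, the 10 H3K27ac regions of all 4 libraries with the most covered bases, and the windows. Bins named outside these windows were chosen after their values were seen.

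The calls of limb-only regions, the shift test and the bin rule were tested on simulated data. Of 200 planted limb-only regions, 100% were recovered for each mark. This followed from the setting, which made them present in both libraries of a limb and absent from the other limb. Among 29871 H3K27ac regions with detection drawn independently per library, 3397 unplanted regions were also called, so a limb-only region of presence and absence is weak evidence alone. For H3K27me3, 2127 of 14776 were. Detection in the lists themselves was shared between libraries, with 5881 H3K27ac and 4092 H3K27me3 regions in all 4. The simulated counts are therefore not expected numbers for the lists, whose limb-only totals were lower, at 1655 and 1420. Of 100 independent placements of 8514 regions, 5% gave a shift-test p under 0.05. The placements were uniform along each chromosome, so this does not cover marks that share broad parts of a chromosome. The bin rule recovered all 200 planted bins of 132009 and called 0 others. Both outcomes followed from the setting: the simulated libraries were copies of a single library with noise too small to reach the 4 kb gap. The planted differences were set above that gap. This simulation therefore gives no error rate for the bin rule. Alternatives covered a stricter score threshold, lists of equal length, a 50% overlap, a merge gap of 1 kb, each library left out in turn and, for H3K27me3, peaks stitched within 3 kb. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.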

Results

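Forelimb and hindlimb buds are built from the same tissues but take on different identities, and the comparisons here ask where an active and a repressive chromatin mark differ between them. Peak lists of 10 libraries were analysed. At E10.5 there were 2 H3K27ac and 2 H3K27me3 libraries per limb, and at E11.5 there was 1 H3K27ac library per limb. The E10.5 H3K27ac lists held 17476 ± 5497 peaks in forelimb and 18000 ± 1186 in hindlimb (mean ± SD, n = 2 each), covering 11.2 ± 4.98 Mb and 10.8 ± 1.80 Mb. The H3K27me3 lists held 11431 ± 1348 peaks in forelimb and 12790 ± 158 in hindlimb (n = 2 each), covering 8.75 ± 1.68 Mb and 12.8 ± 1.05 Mb. Median peak width was 438 to 579 bp for H3K27ac and 551 to 678 bp for H3K27me3. The E11.5 lists held 23209 forelimb and 32612 hindlimb peaks. Chromosomes 2 and 11 carried the largest shares of covered bases for both marks at E10.5, with chromosome 2 at 9.27% ± 0.145 of H3K27me3 in forelimb and 9.25% ± 0.0153 in hindlimb (SD, n = 2 each). The X chromosome held 0.770% ± 0.124 and 1.10% ± 0.112 of H3K27me3, and 0.748% ± 0.193 and 0.673% ± 0.0739 of H3K27ac, in forelimb and hindlimb.

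At the genes of limb identity, the limb with more H3K27ac had less H3K27me3. Tbx5, the T-box transcription factor of the forelimb, was acetylated in forelimb alone and trimethylated in hindlimb alone. In its window on chromosome 5, H3K27ac peaks covered 16.4 ± 3.50 kb in forelimb and 0 kb in both hindlimb libraries, while H3K27me3 covered 0 kb in both forelimb libraries and 28.4 ± 0.0841 kb in hindlimb (SD, n = 2 each). The 2 best ranked forelimb-only H3K27ac regions of the genome were there, at 120251833 to 120256663 and 120284635 to 120290825 (mm9). The best ranked hindlimb-only H3K27me3 region, at 120243817 to 120251680, ended just before the first of these. The next ranked, at 120251692 to 120259494, overlapped that H3K27ac region. Of the 10 best ranked regions, 5 of the forelimb-only H3K27ac set and 7 of the hindlimb-only H3K27me3 set were at Tbx5. At E11.5 the forelimb list covered 29.4 kb of the window and the hindlimb list 0 kb.

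Pitx1, the homeodomain factor of the hindlimb, showed the opposite arrangement. In its window on chromosome 13, H3K27ac covered 0 kb in both forelimb libraries and 13.7 ± 0.375 kb in hindlimb, and H3K27me3 covered 12.9 ± 1.35 kb in forelimb and 2.92 ± 0.161 kb in hindlimb (SD, n = 2 each). The best ranked hindlimb-only H3K27ac region of the genome spanned 55926316 to 55934651 on chromosome 13. The hindlimb did not lack H3K27me3 at Pitx1: both libraries had 7 peaks there, none longer than 543 bp, inside the acetylated interval. At E11.5 the forelimb list again had 0 kb of H3K27ac and the hindlimb list 16.0 kb.

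Tbx4, the hindlimb T-box factor, differed in degree and not in presence. H3K27ac in its window on chromosome 11 covered 4.00 ± 2.40 kb in forelimb and 10.2 ± 3.51 kb in hindlimb, and H3K27me3 covered 7.38 ± 0.221 kb and 1.95 ± 0.123 kb (SD, n = 2 each). The replicates of the limbs did not overlap for either mark. The difference was concentrated at 85700001 to 85720000, where H3K27ac covered 0.619 ± 0.462 kb in forelimb and 5.62 ± 1.08 kb in hindlimb. At E11.5 the window had 12.7 kb of H3K27ac in forelimb and 39.0 kb in hindlimb. Complete separation of 2 libraries from 2 occurs by chance in 33.3% of cases, so no single window is tested by it.

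**Figure D1:**
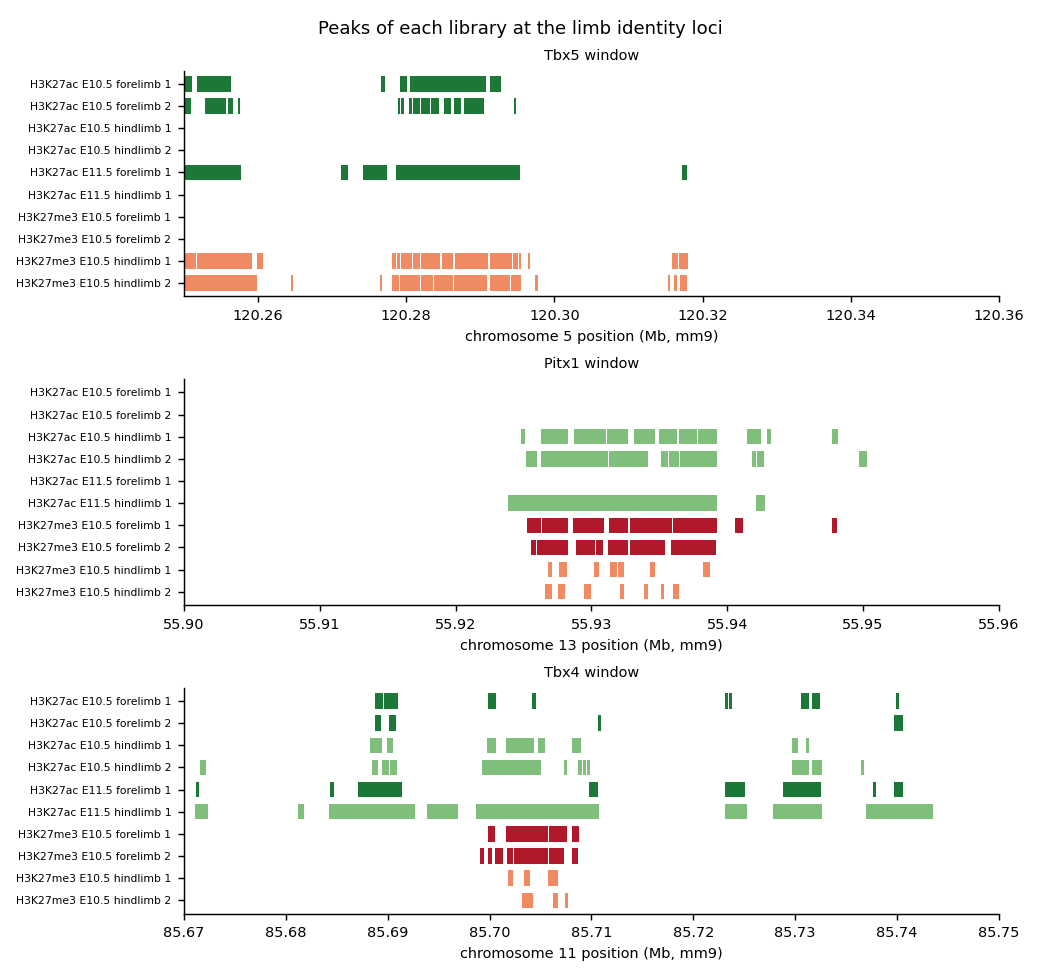
Maps of the Tbx5, Pitx1 and Tbx4 windows, with mm9 position in Mb on the x axis and 1 lane per library; each bar is a peak, green for H3K27ac and red for H3K27me3, dark for forelimb and light for hindlimb. H3K27ac and H3K27me3 occupy the same intervals in opposite limbs at Tbx5 (0 kb of H3K27ac in hindlimb) and Pitx1 (0 kb of H3K27ac in forelimb). E11.5 peaks are wider, and near neighbours appear to have been joined in those lists, but the cause of the width was not tested.

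The Hox clusters, which pattern the body axis and the limb, differed from one another. The HoxC cluster on chromosome 15 had the largest limb difference of the 4. Its H3K27ac covered 7.34 ± 5.27 kb in forelimb and 26.8 ± 6.11 kb in hindlimb, and its H3K27me3 covered 65.6 ± 2.81 kb and 35.9 ± 3.002 kb (SD, n = 2 each), and the limbs' libraries did not overlap for either mark. The H3K27me3 domain began at the Hoxc13 end in both limbs. From 102740001 to 102760000 it covered 14.5 ± 0.876 kb in forelimb and 16.9 ± 0.508 kb in hindlimb. From 102780001 to 102800000 it covered 15.1 ± 1.34 kb in forelimb and 1.73 ± 0.0219 kb in hindlimb, and there H3K27ac covered 0 kb in both forelimb libraries and 12.8 ± 3.96 kb in hindlimb. The next 20 kb had 12.4 ± 0.486 kb of H3K27me3 in forelimb and 0 kb in both hindlimb libraries. Nearer to Hoxc4, from 102840001 to 102860000, H3K27ac covered 3.07 ± 1.999 kb in forelimb and 1.05 ± 0.723 kb in hindlimb.

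The HoxB cluster on chromosome 11 showed a limb difference for H3K27me3 in its middle part. From 96120001 to 96140000, H3K27me3 covered 12.1 ± 0.621 kb in forelimb and 0.407 ± 0.161 kb in hindlimb (SD, n = 2 each), while H3K27ac covered 0 kb in forelimb and 1.21 ± 0.0990 kb in hindlimb. The preceding 20 kb, from 96100001, had 5.92 ± 0.506 kb of H3K27me3 in forelimb and 0 kb in hindlimb. At the Hoxb13 end, from 96040001 to 96060000, both limbs were covered by H3K27me3, at 14.8 ± 0.665 kb and 18.04 ± 0.661 kb. HoxB H3K27ac over the whole window was 9.5 and 7.1 kb in the forelimb libraries and 10.1 and 14.3 kb in the hindlimb libraries. From 96140001 to 96160000 it covered 0.967 ± 0.0891 kb in forelimb and 4.94 ± 1.63 kb in hindlimb. Nearer to Hoxb1, from 96200001 to 96220000, the direction was opposite, at 4.16 ± 0.885 kb in forelimb and 1.82 ± 0.456 kb in hindlimb. HoxA and HoxD, which act in both limbs, carried H3K27ac and H3K27me3 over different parts of the cluster in each limb. In HoxA, H3K27ac covered 15.54 ± 2.10 kb in forelimb and 15.796 ± 2.81 kb in hindlimb from 52160001 to 52180000, with 0 kb of H3K27me3, and at the Hoxa13 end from 52260001 H3K27me3 covered 12.7 ± 0.404 kb and 12.6 ± 1.29 kb. In HoxD, H3K27ac covered 12.9 ± 3.01 kb and 10.96 ± 3.198 kb from 74520001 to 74540000, and H3K27me3 covered 9.57 ± 0.197 kb and 10.7 ± 0.453 kb toward Hoxd13 from 74480001. Over the whole windows, the limbs' H3K27ac libraries overlapped for HoxA and HoxD. HoxA H3K27me3 was higher in both forelimb libraries (36.0 and 29.2 kb) than in both hindlimb libraries (27.6 and 25.3 kb), and HoxD H3K27me3 overlapped between the limbs.

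**Figure D2:**
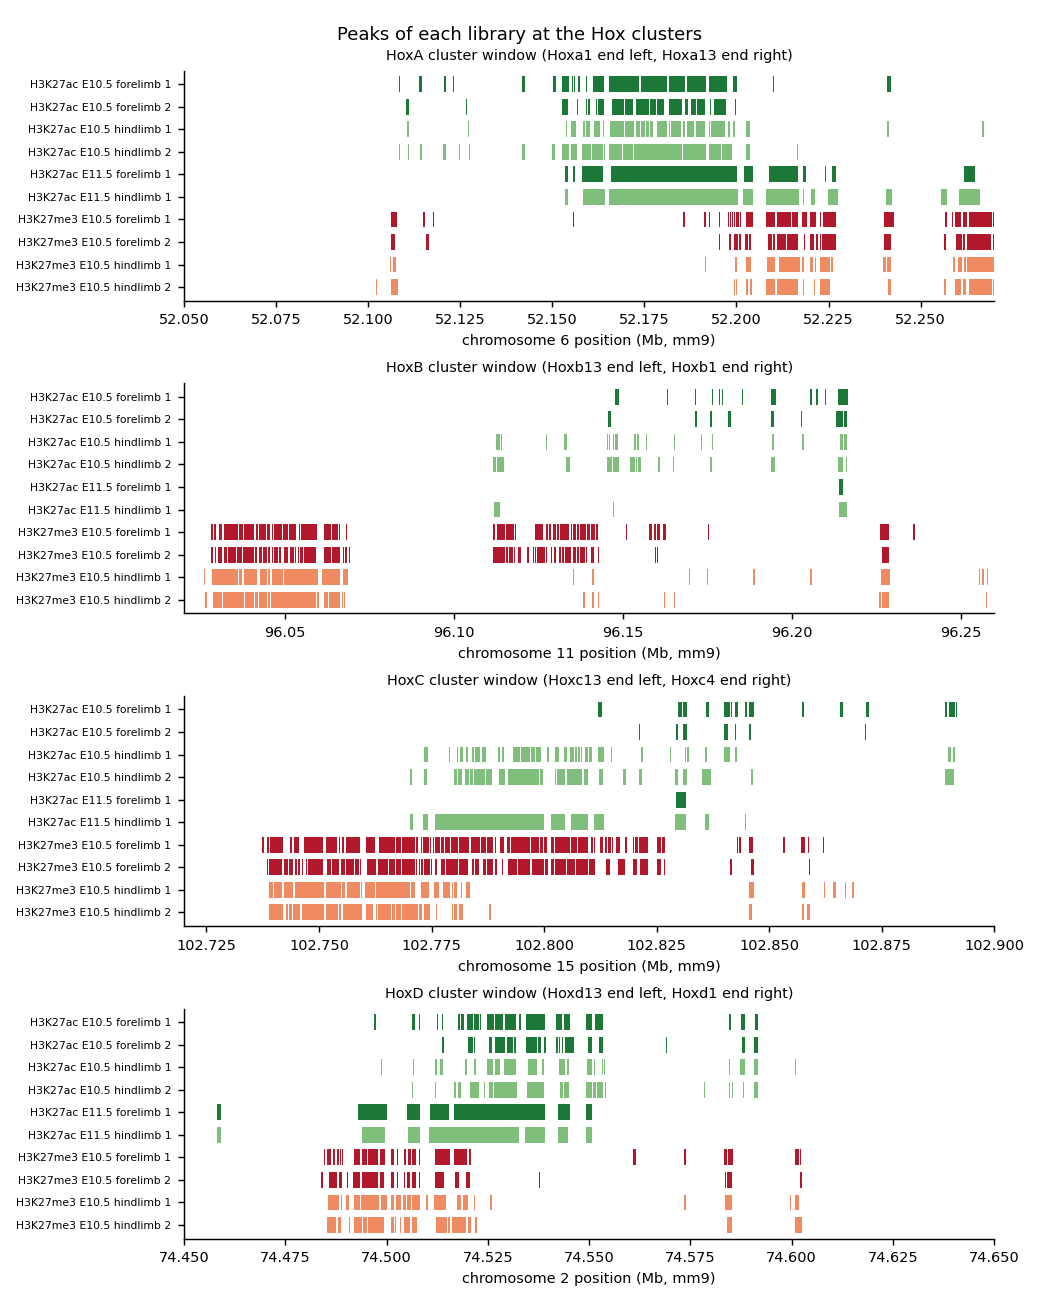
Maps of the HoxA, HoxB, HoxC and HoxD windows, with mm9 position in Mb on the x axis and 1 lane per library; colours are green for H3K27ac and red for H3K27me3, dark for forelimb and light for hindlimb, and the ends are named from the GRCm38.p6 gene order. In HoxC the forelimb H3K27me3 domain runs past 102800001 on chromosome 15, where the hindlimb libraries have H3K27ac, while HoxA and HoxD carry both marks in both limbs, with HoxA H3K27me3 at 32.6 ± 4.80 kb in forelimb and 26.4 ± 1.64 kb in hindlimb (SD, n = 2 each).

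Across the genome, the H3K27ac peak sets as deposited did not separate the limbs more than another pairing of the libraries did. The 4 E10.5 libraries formed 29871 union regions, of which 5881 were detected in all 4, 855 in both forelimb libraries alone and 800 in both hindlimb libraries alone. The limb-only total of 1655 was matched by pairing forelimb replicate 1 with hindlimb replicate 2 against the remaining libraries, which also gave 1655, while the pairing by replicate number gave 1127. With lists of equal length, the limb split had the highest total, 1561 against 1059 and 895. These 3 splits allow no p below 0.333. Jaccard similarity averaged 0.370 within limbs and 0.375 between limbs, and the most similar pair was forelimb 1 and hindlimb 2 at 0.446. Limb-only regions had a median score percentile within their own lists of 42.5 for forelimb and 41.6 for hindlimb. Of the 10 best ranked, 5 forelimb-only regions lay at Tbx5 and 5 in no window, and 8 hindlimb-only regions lay in the HoxC, HoxB or Pitx1 windows. The counts moved by over 1.5 times with the top 50% of each list, to 506 forelimb-only and 488 hindlimb-only regions, and without single libraries they were 1400 to 7205 and 1058 to 5128.

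For H3K27me3, the limb split had the highest count of the 3, and this came from the hindlimb pair. Of 14776 union regions, 4092 were detected in all 4 libraries, 161 in forelimb alone and 1259 in hindlimb alone. The limb-only total of 1420 compared with 344 and 308 for the other splits, and Jaccard similarity averaged 0.608 within limbs against 0.532 between limbs (exact p = 0.333, one-sided, the smallest that 3 splits allow). The hindlimb libraries were the most similar pair, at 0.658. The forelimb libraries, at 0.558, were less similar to each other than forelimb 1 was to either hindlimb library (0.562 and 0.576), and forelimb 1 shared more regions with hindlimb 1 alone (281) than with forelimb 2 alone. Without forelimb replicate 2 the direction turned, with 2171 forelimb-only and 1535 hindlimb-only regions. That count sets a single forelimb list against a hindlimb pair, which by itself raises the forelimb-only number. Leaving out forelimb replicate 1 makes the same setting and gave 854 forelimb-only and 2237 hindlimb-only regions. The direction therefore depended on which forelimb list was kept. Of the 161 forelimb-only regions, 41 (25.5%) lay in the 18 windows, compared with 18 (1.43%) of the 1259 hindlimb-only regions, a count made after the lists were seen. Neighbouring pieces of a domain count separately here, and a merge gap of 1 kb left 70 forelimb-only and 678 hindlimb-only regions. Among the 10 best ranked, 9 forelimb-only regions lay in the HoxC or HoxB windows and 7 hindlimb-only regions at Tbx5. The remaining forelimb-only one was at 117095029 to 117096109 on chromosome 13, outside the windows. The median score percentile was 34.3 for forelimb-only and 36.6 for hindlimb-only regions. Forelimb libraries also covered fewer bases than hindlimb libraries in the 4092 regions common to all 4, with 7.58 ± 0.879 Mb against 9.70 ± 0.423 Mb (SD, n = 2 each).

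**Figure D3:**
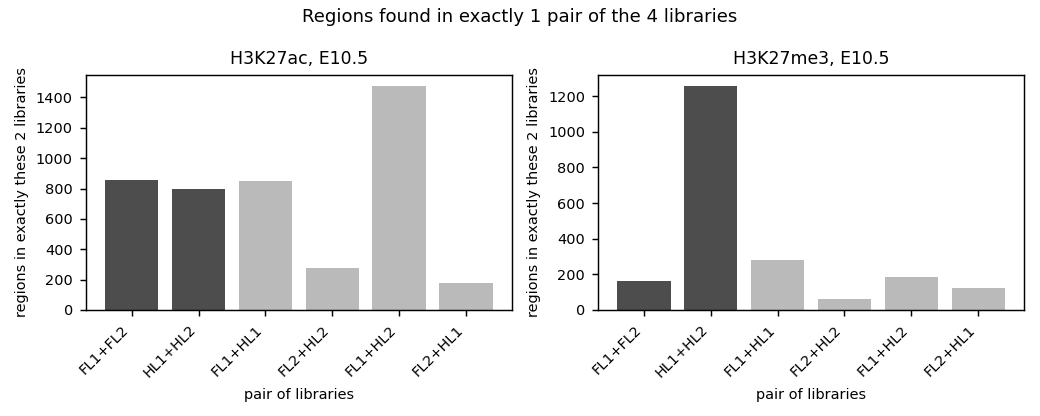
Number of regions (y axis) detected in exactly the pair of libraries named on the x axis (FL forelimb, HL hindlimb, with replicate number) for H3K27ac and H3K27me3 at E10.5; dark bars are the pairs of 1 limb. For H3K27ac the pair FL1 and HL2 has the highest bar (1477), and for H3K27me3 the hindlimb pair has (1259).

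Large differences in covered bases were few and lay mostly at named loci for H3K27ac and for forelimb H3K27me3. Of 132009 bins of 20 kb, 5 differed by at least 4 kb for H3K27ac, 2 higher in forelimb and 3 in hindlimb, and 20 differed for H3K27me3, 7 higher in forelimb and 13 in hindlimb. At this gap the other splits of the libraries gave 0 bins for either mark. At gaps of 2 and 1 kb, pairing forelimb 1 with hindlimb 2 gave 21 and 233 H3K27ac bins, more than the 8 and 44 of the limbs. With lists of equal length, that pairing gave 10 and 129 against 10 and 71. For H3K27me3 the limbs gave 130 and 634 bins at these gaps, and each other split at most 2 and 14. All 5 H3K27ac bins also differed for H3K27me3, in the opposite limb: 2 at Tbx5, 1 at Pitx1 and 2 in HoxC. The 2 H3K27ac lists at E11.5 differed in the same direction at all 5. Of the 7 bins with more H3K27me3 in forelimb, 6 lay in the Pitx1, Tbx4, HoxB and HoxC windows. The remaining one, at 117080001 to 117100000 on chromosome 13, had 8.70 ± 0.270 kb of H3K27me3 in forelimb and 1.23 ± 0.00990 kb in hindlimb, against H3K27ac of 0 kb and 1.367 ± 0.103 kb (SD, n = 2 each). Of the 13 bins with more H3K27me3 in hindlimb, 3 lay in the Tbx5 and Lmx1b windows, and 10 of the 13 had peaks in both forelimb libraries too. At Lmx1b, the LIM homeodomain gene of dorsal limb identity, the bin at 33480001 to 33500000 on chromosome 2 had 1.45 ± 0.188 kb in forelimb and 6.98 ± 1.01 kb in hindlimb, while H3K27ac was 10.4 ± 3.27 kb and 8.78 ± 0.315 kb. With coverage scaled to equal library totals, the forelimb and hindlimb counts for H3K27me3 became 11 and 5. The Lmx1b bin did not meet the 4 kb rule with this scaling.

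**Figure D4:**
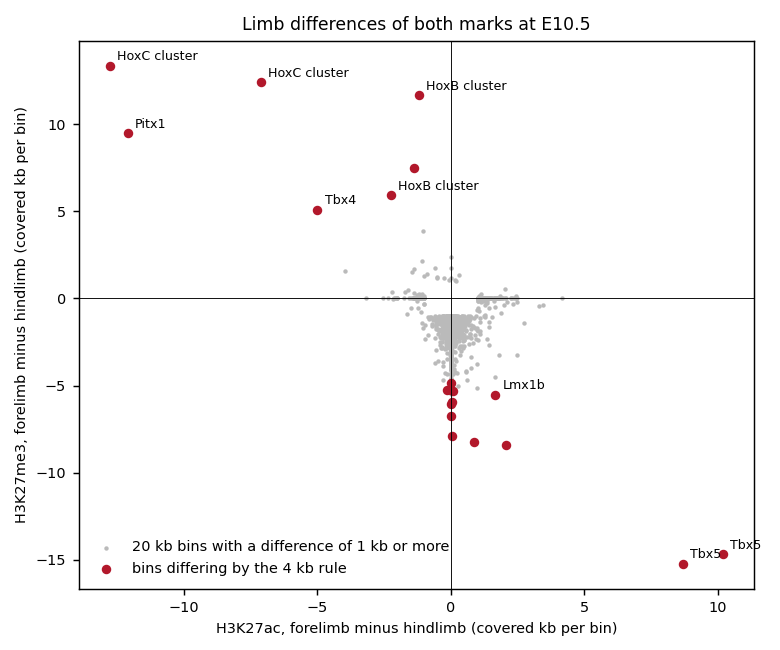
Forelimb minus hindlimb mean covered kb per 20 kb bin at E10.5, H3K27ac on the x axis and H3K27me3 on the y axis (n = 2 libraries per limb and mark); grey points are bins that differ by at least 1 kb in either mark, red points meet the 4 kb rule and carry their window's name where they have one. The bins of Tbx5 lie at the lower right and those of Pitx1 and HoxC at the upper left, so the 5 bins called for both marks differ in opposite directions.

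Limb-only H3K27ac regions were compared with limb-only H3K27me3 regions within 10 kb, to ask whether acetylation in 1 limb goes with trimethylation in the other. Of 855 forelimb-only H3K27ac regions, 50 lay near hindlimb-only H3K27me3 alone and 0 near forelimb-only H3K27me3 alone. Of 800 hindlimb-only regions, 27 lay near forelimb-only H3K27me3 alone and 23 near hindlimb-only H3K27me3 alone (Fisher's exact test, two-sided, p = 1.13e-10; the 95% interval of the odds ratio had a lower bound of 12.96). The hindlimb side rested on few places: the 27 regions formed 9 groups when joined within 100 kb, with 14 regions in HoxC and 5 in HoxB. The forelimb regions were scattered, since the 52 near any hindlimb-only H3K27me3 formed 44 groups and only 6 were at Tbx5. More than 90% of limb-only H3K27ac regions, 93.9% in forelimb and 93.8% in hindlimb, had no limb-only H3K27me3 of either kind within 10 kb. Leaving out single libraries lowered the odds ratio, computed with 0.5 added to each count, from 118 to between 3.03 and 6.22, and it was 19.6 at equal lengths, 5.31 within 50 kb and 26.3 without regions near the windows (43 and 0 against 21 and 6). Hindlimb-only H3K27me3 regions outnumbered forelimb-only ones 1259 to 161. A neighbour of the former kind is therefore the more frequent one by number alone, for both sets of H3K27ac regions. This bears on the counts within each set, while the odds ratio compares the sets.

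Within a limb, the marks overlapped at few regions but at more than shifted positions gave. Each library pools the cells of limb buds. Overlap, and both marks at a locus, can therefore come from different cells and does not show both marks together. The shifts run along whole chromosomes, so marks that share broad parts of a chromosome would also exceed them. In forelimb, 121 of 8514 H3K27ac regions of both replicates (1.42%) touched H3K27me3, against 47.5 ± 7.90 (SD over shifts) in 1000 circular shifts, 2.55-fold more (two-sided permutation p = 0.002, the smallest these shifts can give). In hindlimb, 292 of 9115 regions (3.204%) did, against 70.5 ± 10.2, 4.14-fold more (permutation p = 0.002, also the smallest). With the top 50% of each list, the forelimb excess was 1.04-fold (permutation p = 0.893), so that call rests on lower-scoring peaks, and the hindlimb excess was 2.08-fold (permutation p = 0.002). Without forelimb replicate 2 the forelimb excess was 5.27-fold. Control loci carried 1 mark. Pax6, a regulator of eye and neural development, had 24.8 ± 2.57 kb of H3K27me3 in forelimb and 30.5 ± 0.919 kb in hindlimb, and 0 kb of H3K27ac in all 4 libraries (SD, n = 2 each). The housekeeping genes Actb and Gapdh had the reverse, with 3.76 ± 0.367 kb and 3.65 ± 0.392 kb of H3K27ac at Actb, 2.60 ± 0.849 kb and 2.03 ± 0.376 kb at Gapdh, and 0 kb of H3K27me3 in all 4 libraries. Shh, whose expression in the limb is limited to a small posterior zone, had 9.51 ± 1.14 kb and 11.3 ± 0.0445 kb of H3K27me3 in its gene window and 0 kb of H3K27ac at E10.5. Hand2, a posterior regulator upstream of Shh, carried both marks in both limbs: H3K27ac covered 4.61 ± 1.27 kb and 4.69 ± 2.89 kb, and H3K27me3 4.11 ± 0.182 kb and 5.28 ± 2.06 kb.

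The E11.5 lists served to follow H3K27ac over a day and to check limb-only calls in separate libraries. Of H3K27ac regions found in both E10.5 replicates, 90.7% were covered at E11.5 in forelimb (7725 of 8514, 95% Wilson interval 90.1 to 91.3%) and 92.6% in hindlimb (8445 of 9115, 92.1 to 93.2%). These intervals cover counting error only. Between E10.5 replicates in forelimb, 45.7% of replicate 1 peaks were found in replicate 2 and 79.6% of replicate 2 peaks in replicate 1. In hindlimb these were 64.5% and 56.8%. They are shares of all peaks of a list, and not of regions found in both replicates. On that basis, 74.48% of replicate 1 and 82.7% of replicate 2 peaks were covered at E11.5 in forelimb, and 78.4% and 82.9% in hindlimb. The E11.5 lists covered 31.3 Mb in forelimb and 47.2 Mb in hindlimb, against 7.63 to 14.7 Mb in the E10.5 H3K27ac lists. Conversely, 51.9% of forelimb and 63.9% of hindlimb E11.5 peaks were in neither E10.5 replicate. Antibody lot and list making differ between the stages, so these shares do not measure a change with age.

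Limb-only regions of E10.5 mostly had a peak in both E11.5 lists, which does not show equal acetylation. Of the 855 forelimb-only regions, 72.2% lay in both E11.5 lists and 14.6% in neither. Of the 800 hindlimb-only regions, 57.3% lay in both and 23.5% in neither. Among those in a single E11.5 list, 26 forelimb-only regions were in the forelimb list and 87 in the longer hindlimb list, compared with 13 and 141 for hindlimb-only regions (odds ratio 3.23, 95% interval 1.51 to 7.23, Fisher's exact test, two-sided, p = 0.00136). Without regions within 20 kb of the windows, the counts were 20 and 87 against 13 and 121 (Fisher's exact test, two-sided, p = 0.0585), so the call rests partly on the loci described above. Without single libraries the odds ratio, with 0.5 added to each count, was 1.76 to 2.30 against 3.17. The 5 best ranked forelimb-only regions at Tbx5 and the 8 best ranked hindlimb-only regions in windows were each found in the matching limb alone at E11.5. The remaining 5 and 2 of the 10 best ranked were in both lists. Those in windows came from Tbx5, Pitx1, HoxC and HoxB only, and neighbouring regions are not separate checks. Single E11.5 peaks spanned several of them, as from 120278579 to 120295423 at Tbx5 and from 55923885 to 55939220 at Pitx1. In limb regulators active in both limbs, E11.5 lists had H3K27ac over Hand2 (20.1 kb in forelimb, 24.7 kb in hindlimb) and Lmx1b (23.1 and 28.1 kb). Gli3, the Hedgehog pathway repressor, had 4.14 ± 0.744 kb and 3.79 ± 0.553 kb at E10.5 (SD, n = 2 each), and 10.9 and 20.2 kb at E11.5. Meis1 and Meis2, homeobox genes of the proximal limb, had 6.83 ± 2.47 kb and 4.27 ± 0.325 kb in forelimb at E10.5 and 1.20 kb and 0 kb at E11.5. In hindlimb they had 9.86 ± 2.86 kb and 7.34 ± 1.49 kb at E10.5 and 5.87 and 6.35 kb at E11.5. Covered bases are not comparable between the stages, so these are values of each list.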

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

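The HoxC window was singled out because its H3K27ac coverage differed between the stages in opposite directions in the limbs, a difference that was not tested. In forelimb the E11.5 list covered 2.206 kb, below both E10.5 libraries (11.1 and 3.62 kb), and in hindlimb it covered 38.511 kb, above both (22.5 and 31.2 kb). With 1 library per limb at E11.5, another antibody lot and peaks that appear to have been joined, no explanation was tested. It was the only one of 18 windows with this pattern. No group of samples was large enough for a test of outlying libraries.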

How the results depend on the processing

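Alternatives were listed before the data were examined, except those on bins, the removal of windows, the window differences and crossed replicate numbers, which were chosen after seeing the data. Limb-only regions depend strongly on having both replicates, since leaving 1 out turns a pair into a single library: without single libraries the counts ranged from 1400 to 7205 (H3K27ac forelimb), 1058 to 5128 (H3K27ac hindlimb), 256 to 2171 (H3K27me3 forelimb) and 1535 to 4667 (H3K27me3 hindlimb). With the top 50% of each list they were 506, 488, 72 and 699. A merge gap of 1 kb gave 70 and 678 for H3K27me3 and, for H3K27ac, stayed within 1.5 times, as did equal lengths and the 50% overlap for both marks. The hindlimb H3K27me3 count exceeded the forelimb count in each of these alternatives except without forelimb replicate 2, where it was 1535 against 2171; a cut of own-limb lists to their top 25%, weighed with the other observations, also turned it (10 against 15).

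The deviations of same-numbered libraries correlated at -0.216 (H3K27ac) and 0.121 (H3K27me3) over bins, and with 2 replicates the numbers were not taken to pair the samples. The replicate block left the counts at 855, 800, 161 and 1259 by construction, and so did crossed numbers for H3K27ac (855 and 800). Within-limb minus between-limb similarity under the replicate block was 0.00862 for H3K27ac and 0.0738 for H3K27me3, and every similarity alternative differed from the reported value by less than the SD between pairs of libraries, with the H3K27ac difference on either side of 0.

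The overlap of marks kept its call except in forelimb with the top 50% of each list (1.04-fold). The hindlimb value there was 2.08-fold. Without single libraries it was 2.78 to 5.27-fold in forelimb and 5.25 to 5.65-fold in hindlimb. The E11.5 odds ratio, with 0.5 added to each count, was 3.17, ranged from 1.76 to 2.30 without single libraries, and lost its call without the windows (2.11), where fewer regions were tested. The odds ratio of H3K27me3 in the other limb kept its call throughout, from 3.03 to 6.22 without single libraries, 5.31 within 50 kb and 26.3 without the windows. The share of E10.5 regions covered at E11.5 was 95.1% in forelimb and 96.1% in hindlimb with the top 50%, 92.7% and 94.1% at equal lengths, and 88.7% and 91.2% at 50% overlap. Single libraries gave 74.48 to 82.7% and 78.4 to 82.9%. Stitching within 3 kb gave 4637 forelimb and 5585 hindlimb H3K27me3 peaks.

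Bins moved with the gap. At 2 kb, H3K27ac had 3 bins higher in forelimb and 5 in hindlimb, fewer than the 21 from pairing forelimb 1 with hindlimb 2, and H3K27me3 had 122 higher in hindlimb. At 1 kb the counts were 21 and 23 for H3K27ac and 11 and 623 for H3K27me3, and that pairing gave 233 H3K27ac bins. In 50 kb bins there was 1 H3K27ac bin higher in forelimb and 39 H3K27me3 bins higher in hindlimb, and scaled coverage gave 11 and 5 for H3K27me3. Without single libraries the ranges were 2 to 4 and 3 to 5 for H3K27ac, and 7 to 8 and 14 to 47 for H3K27me3. No window difference with separated replicates turned its direction with the top 50% or at equal lengths; leaving out a library cannot turn one. The cause of these movements was not tested beyond the explanations weighed elsewhere. Promoter windows of 2.5 kb need mm9 gene models and were not run. Depth is unknown and limits every statement on absent peaks.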

Other observations

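The bins outside the windows with more H3K27me3 in hindlimb held peaks in both limbs, with 1 exception on chromosome 11. With coverage scaled to equal totals, 5 bins of the genome were higher in hindlimb. The bin at 99040001 to 99060000 on chromosome 3 had 2.73 ± 1.21 kb in forelimb and 11.1 ± 0.754 kb in hindlimb, beside H3K27ac of 4.78 ± 1.03 kb and 2.70 ± 0.530 kb. The exception, at 77760001 to 77780000 on chromosome 11, had 0 kb in forelimb and 6.07 ± 0.647 kb in hindlimb, with no E10.5 H3K27ac. The bin at 63300001 to 63320000 on chromosome 1 had 4.87 ± 0.522 kb and 12.7 ± 2.31 kb (SD, n = 2 each). With scaled coverage this bin did not meet the 4 kb rule. The H3K27ac region of all 4 libraries with the most covered bases lay in HoxA, at 52165268 to 52185364 on chromosome 6. The longest H3K27me3 region of all 4 libraries lay at 94077410 to 94096230 on chromosome 16.

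Equal lengths were chosen before the data were examined, but their reading as tests of list length, and the cuts of own-limb lists, were chosen after the results had been seen; those on common regions, fixed width and mixed pairs were set out beforehand. Hindlimb-only H3K27me3 regions outnumbered forelimb-only ones, 1259 to 161. Cutting the lists to equal lengths left 944 against 181, a ratio of 5.22 (95% interval 4.45 to 6.11, counting error only). This argues against the number of peaks as the whole cause. The cut does not set covered bases equal, so it does not test them. They were 8.75 Mb in forelimb and 12.8 Mb in hindlimb in the lists as deposited. With coverage scaled to equal totals, 11 bins were higher in forelimb and 5 in hindlimb by the 4 kb rule. Without 1 library the ratio at equal lengths was 1.69 (forelimb 1), 0.835 (forelimb 2), 7.06 (hindlimb 1) and 12.2 (hindlimb 2). These set a single list against a pair, which moves the ratio at any length. In that same setting the forelimb lists did not give the same direction. Weaker enrichment in the forelimb libraries may contribute: in regions common to all 4 libraries they covered 0.781 times the bases of the hindlimb libraries, with both forelimb libraries below both hindlimb libraries. Cutting the lists of the limb that has a region did not settle it: forelimb and hindlimb counts were 84 and 669 with the top 75%, 29 and 173 with the top 50%, and 15 and 10 with the top 25%. A difference between the limbs in development stays open and untested.

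Pairing forelimb 1 with hindlimb 2 gave as many H3K27ac regions as the limbs did. These libraries have the longest lists and widest peaks. At equal lengths the tie was gone, with a crossed total of 0.678 times the limb total (1059 against 1561), so list length may account for it. The pair of forelimb 1 and hindlimb 2 had 8.30 times the regions of the other crossed pair in the lists as deposited, 3.04 times at equal lengths, and 2.39 times with every peak also set to 500 bp. These values argue against length or width as the whole cause of that excess alone. The labels give these libraries different multiplex indices, and what they share was not tested.

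Most limb-only H3K27ac regions lay in both E11.5 lists (65.0% of 1655). Missed detection in single E10.5 libraries could produce this, since 66.9% of the 2782 regions found in a pair of libraries that mixes the limbs were in both lists too, against 37.2% of regions of 1 library alone. A true loss of limb preference between the stages stays open, because stage, lot and list making cannot be told apart.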
